A study of Rattus norvegicus with 8 samples.

How the data were processed

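Total RNA of the hypothalamic paraventricular nucleus of 4 male and 4 female rats was labelled with Cy3 or Cy5 and hybridised to two-colour Agilent arrays, per the labels' protocols. Scanned images were processed with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The background treatment, the filter behind the missing values and the normalization are not given in the sources used here. The series design text counts 4 biological replicates per sex. The labels do not say how many litters they came from.

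The table deposited by the authors gives 1 log2 value per feature and sample. The log base was read from the values: 2 to the power of a low value fell on whole multiples of 1 step per sample in 100% of values under 1000 steps, within 0.05 steps. Spacings read with the natural base or base 10 fell on a step in 11.6% to 13.0% and 6.55% to 7.00%. The values are thus log2 of a whole-number signal over a reference level per sample. That level was 1566 to 2254.5 steps in Cy3 and 2437.5 to 2674 steps in Cy5. Features were not centred. The median over the features with a value in all samples was -0.40 to -0.37 in Cy3 samples and -0.46 to -0.45 in Cy5 samples. By the rule set before the data were examined, medians this close were left as they are. The direction needs no dye ratio, since each value belongs to 1 sample. Whether background was subtracted before the logarithm is unknown, and in Cy3 the values crowd at a low level of -3.15 to -2.55, so differences of dim features in Cy3 are compressed if background remains there. In Cy5 the densest low level was -5.05 to -4.75 in 3 samples and -1.25 in female replicate 2. It was sought among low values only, and -1.25 lies near the upper end of the range searched, so it need not be a background level. The 5th percentile was -3.31 to -2.72 in Cy3 and -4.83 to -4.75 in Cy5.

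The features are numbered up to 45220, and 966 numbers are not in the table. Feature numbers are not paired with gene names in the files, and the gene table of the rat reference holds no feature numbers, so 0 features could be named. The 28 gene lists and cell type markers fixed before the data were examined could not be tested, nor could the choice among probes of a gene, and the planned fit per gene was made per feature. Of 44254 features, 1377 had no value in any sample. A feature was tested if at least 3 samples of each sex had a value, which left 33702 and excluded 10552. The number of arrays limits the precision.

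Sex differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with sex and dye as terms and the array as a random block. The consensus correlation within arrays was 0.136, with 5 residual and 2.95 prior degrees of freedom. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Differences are male minus female on the log2 scale. Within-sex variability was the median over 32011 features with a value in all samples of the SD per sex after removal of the dye means, and the deviations per sample were compared with a two-sided exact permutation test. Named features follow the rule fixed before the data were examined for a table with no gene names: at most 2 per direction, by log2 difference among calls whose samples do not overlap, or, where fewer than 5 features pass in a direction, by moderated statistic, said not to have passed where they did not. No pair of samples held the same values, the largest share of identical values being 0.012%.

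The tests were tried on simulated data for 33702 features, 200 of them changed between the sexes. limma recovered 18% of those with a log2 difference of 0.5, 86% at 1, 96% at 1.5 and 100% at 2. Of its 154 calls, 2.6% were false. The simulated features were independent, with the same variance in both sexes and no pattern over the array or between slides. These shares thus need not hold for the arrays of the series. Separate simulations of 5000 features showed that the array correlation is estimated too low in this layout, a value of 0.208 giving the estimate of 0.1355 seen in 5000 features of the data. The simulations of 33702 features also showed that removing the dye means over all samples draws a true variability ratio of 1.5 to 1.35, whereas removing them within each sex gives 1.50.

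Replicate numbers are shared by males and females. The labels tie no number to a litter or day and each number fixes the dye, so the fit had no replicate block. Alternatives fixed before the data were examined were: no array block, array means, no dye term, each dye alone, a replicate block, quantile normalization, median centring, a filter on the 30% dimmest features, complete features only, eBayes with trend and robust, other thresholds, and leaving out each sample and each array. Added after the data were examined were normexp background correction with an offset of 50, leaving out features that differed by over 1 on the log2 scale between the arrays of a sex, the simulated array correlation, dye means removed within each sex, and subtraction of a local median. The last used the features up to 2 rows and 2 columns away with 85 features to a row. That layout was read from the sex differences, whose rank correlation between features was 0.193 at 85 numbers apart and 0.200 at 170, against 0.0234 at 42 and 0.00320 at 127. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.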

Results

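The series measured gene expression in the hypothalamic paraventricular nucleus, the nucleus that holds the neuroendocrine neurons releasing corticotropin-releasing hormone, vasopressin and oxytocin. The tissue came from Sprague-Dawley rats on postnatal day 15. All 8 animals had been exposed before birth to betamethasone, a synthetic glucocorticoid, given to the dams as 2 injections of 0.4 mg/kg on gestational day 15. The pups received saline on postnatal days 13 to 15 and had no induced spasms. The series title asks how prenatal betamethasone remodels synaptic transmission genes. The samples analysed here hold no animals without betamethasone, so sex was the 1 comparison the design gave: 4 males against 4 females.

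Each sample was 1 colour of an Agilent array, and 2 samples of the same sex shared each of the 4 arrays, replicates 1 and 3 in Cy3 and replicates 2 and 4 in Cy5. The deposited table held 44254 array features. Cy3 samples had 42738 to 42863 values each and Cy5 samples 33617 to 34560, and 6333 features had a value in all 4 Cy3 samples and in no Cy5 sample. Between 13929 and 13950 features per sample lay above the log2 value of 0, the reference level of each sample. The choice of that level may itself set this count, so it is not a measure of agreement between samples. Across features, which are not independent replicates, samples of the same sex and dye correlated at r = 0.984 to 0.995, and samples of the other sex and the same dye at r = 0.984 to 0.991. Samples in the other dye correlated at r = 0.968 to 0.984. The files do not pair the features with gene names, so the features are reported by number and no gene group is described.

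Males and females, by the sex given in the sample labels, had close to the same profile. Of 33702 features tested, 5 differed between the sexes, 1 higher in males and 4 higher in females (limma, Benjamini-Hochberg adjusted p under 0.05). These 5 differed by 0.82 to 1.47 on the log2 scale, and in each of them the 4 male and the 4 female values did not overlap. The median absolute difference between the sexes over all features was 0.11 on the log2 scale, against a median standard error of 0.12, and 96.4% of features lay within 1.5-fold. At an unadjusted p under 0.05 there were 4064 features, 1999 higher in males and 2065 higher in females, where chance alone gives about 1685. Over features complete in all samples the real split gave 4127, and mixed-sex splits that divided an array reached 5727 and 5607. Most other splits gave fewer, and the other pairings of whole arrays gave 636 and 886. A count this high was thus not particular to the split by sex. The direction of the 4064 features changed with place on the array. Those higher in females numbered 655, 587, 555 and 268 from the lowest to the highest of 4 equal blocks of feature numbers. Those higher in males numbered 390, 503, 435 and 671. Among features with a value in all samples, the 4 male and 4 female values did not overlap in 4.72%, where chance gives 2.86%. Within each dye, the 2 male and 2 female values did not overlap, in the same direction in both dyes, in 14.65%, where chance gives 5.56%. Both chance rates take the samples as independent, which samples of 1 array or 1 dye are not. All male arrays lay on 1 slide and all female arrays on another, so sex and slide cannot be told apart in any of these values. The call did not hold with arrays as the units: limma called 0 features on the means of 2 arrays against 2 (3449 at an unadjusted p under 0.05), and 3, all higher in females, with the array correlation that simulated data gave. Without 1 sample the count ranged from 0 to 146, the highest without female replicate 3, and without 1 array it was 9 or 1 (male arrays), 2801 (female replicates 1 and 2) or 6367 (female replicates 3 and 4). The fits with 2801 and 6367 calls kept 1 female array, so they held no spread between female arrays. Their array correlations were negative, at -0.398 and -0.353, so these counts are no measure of a sex difference.

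Feature 3851 was higher in females in all 4 against 4 samples. Its log2 value was 2.10 ± 0.072 (SD, n = 4) in females and 0.90 ± 0.064 (SD, n = 4) in males, a difference of -1.21 (SE 0.077, limma adjusted p = 0.00928) or 2.31-fold. Feature 7496 was 2.34-fold higher in females, at 0.12 ± 0.079 (SD, n = 4) against -1.11 ± 0.13 (SD, n = 4) in males, with a difference of -1.23 (SE 0.099, limma adjusted p = 0.0218). The difference of feature 3851 was -1.16 among Cy3 samples and -1.25 among Cy5 samples, and that of feature 7496 was -1.08 and -1.37. On array means the limma adjusted p was 0.0884 for both. The features that surround these 2 on the array had a median difference of -0.04 around each. Of the 16 around feature 3851, 10 were higher in females, 0 of them by over 0.5. Of the 19 around feature 7496, 12 were higher in females, 1 of them by over 0.5. Feature 7495, which lies beside feature 7496, was itself called higher in females after quantile normalization. Both lay in the lowest of 4 equal blocks of feature numbers, which also held more of the female-higher features called after quantile normalization than any other block.

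Feature 7388 was the 1 called feature with the higher value in males, at -0.67 ± 0.12 (SD, n = 4) against -1.49 ± 0.082 (SD, n = 4) in females. The difference was 0.82 (SE 0.079, limma adjusted p = 0.0491) or 1.77-fold. The 19 measured features surrounding it had a median male excess of 0.23. Of these, 15 were higher in males, 4 of them by over 0.5. After quantile normalization, features 7303, 7473, 7558, 7813 and 7898 were also called higher in males. Together with feature 7388 they lay in column 78, rows 86 to 93. Feature 7301, in row 86 and column 76, was called higher in females. An effect of place on the array surface thus stays open for feature 7388. With the local median of the surrounding features subtracted, the difference of feature 7388 was 0.62 and its limma adjusted p was 0.0810. The limma adjusted p of feature 7388 was 0.107 on array means and 0.0750 with the array correlation from simulated data. Feature 40650 ranked next among male-higher features by moderated statistic and did not pass, with a difference of 0.66 (SE 0.076, limma adjusted p = 0.0811).

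**Figure D1:**
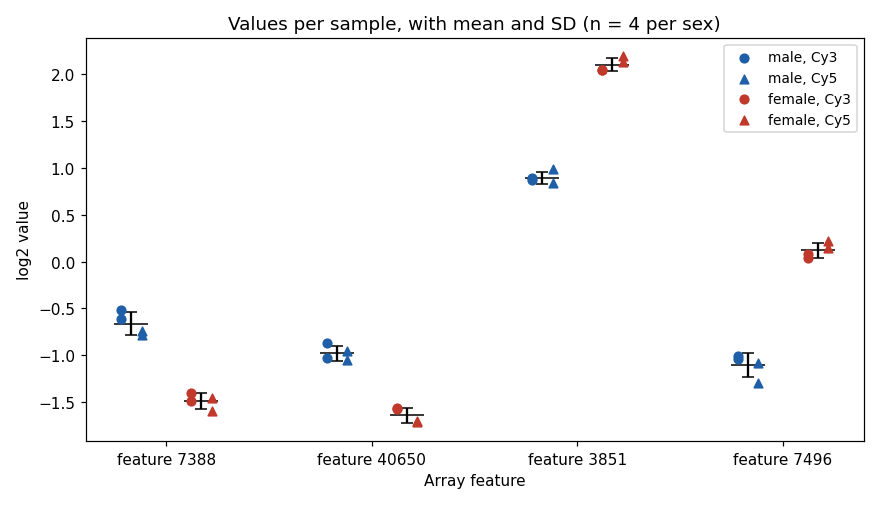
Log2 value (vertical axis) of the 4 named features (horizontal axis) in each sample, males in blue and females in red, Cy3 as circles and Cy5 as triangles, with the mean and SD of each sex (n = 4). For feature 3851 the female values lie between 2.04 and 2.19 and the male values between 0.84 and 0.98.

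The called features were not the ones with the largest differences. There were 296 features with a 2-fold or larger difference, 165 higher in males and 131 higher in females. With features put in 3 groups of equal size by mean level, 0 of the 11234 dimmest were called by limma, 4 of the middle group and 1 of the brightest. The counts at an unadjusted p under 0.05 in these groups were 1571, 1488 and 1005. Standard errors were larger among the dimmest features, with a median of 0.15 against 0.099 among the brightest.

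**Figure D2:**
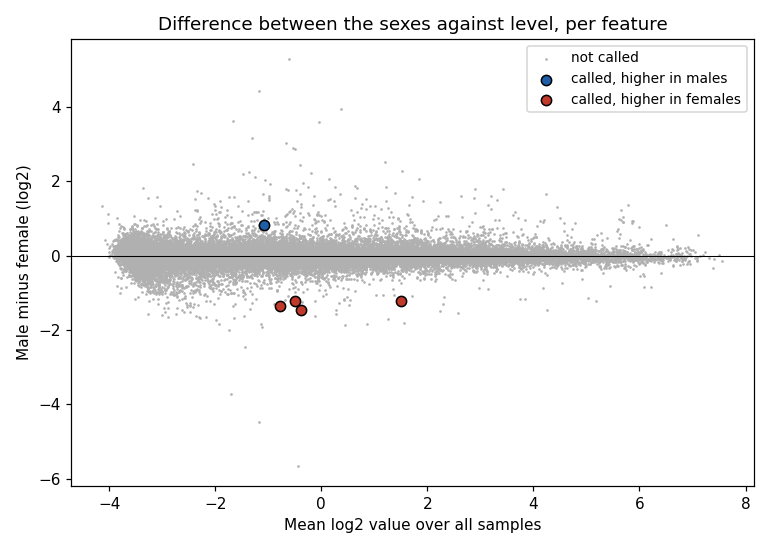
Male minus female difference (vertical axis, log2) of each tested feature against its mean value over all samples (horizontal axis, log2). The 1 called feature higher in males is blue and the 4 called features higher in females are red; the grey points are the other tested features.

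The number of called features depended on how the values were scaled, and the added calls lay mainly on the female side. After quantile normalization between samples, limma called 641 features, 74 higher in males and 567 higher in females, so 88.5% were higher in females against 80.0% of the 5 called in the values as deposited. After normexp background correction, 682 were called, 37 higher in males and 645 higher in females (94.6%). Of the 645, 520 were among the dimmest 11234 features. The median difference of all these dimmest features was -0.17 after normexp and 0.02 as deposited, so normexp moved them as a whole to the female side. The female-higher sets of both scalings shared 500 features; both come from the same samples. The median difference of the 567 features was -0.67 after quantile normalization and -0.65 in the values as deposited. As deposited, all 567 were higher in females and 523 had an unadjusted p under 0.05. They were picked for this direction in the same samples and dyes, so these counts and the medians per dye are not separate support. Their median standard error was 0.194 as deposited and 0.0912 after quantile normalization, against 0.115 and 0.108 over all features. Of the 567, 439 were among the dimmest 11234 features. In both dyes their median difference lay on the female side, at -0.68 in Cy3 samples and -0.66 in Cy5 samples.

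These features were not spread evenly over the array. With feature numbers put in 4 blocks of equal length, the female-higher calls after quantile normalization numbered 237, 207, 114 and 9 from the lowest to the highest numbers, while the dimmest features numbered 2971, 2802, 2714 and 2747. In 1000 random draws of as many features of the same level, the last block held 105 to 174. The male-higher calls numbered 14, 11, 16 and 33.

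**Figure D3:**
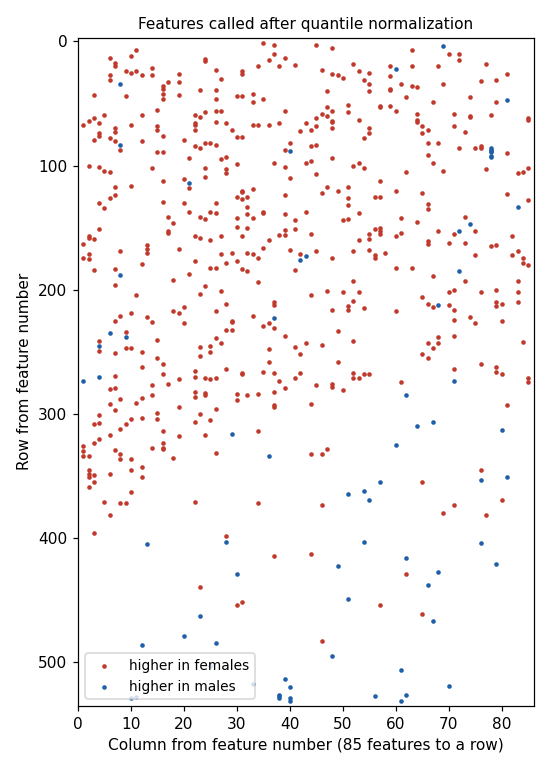
Place of the features called after quantile normalization, by column (horizontal axis) and row (vertical axis) as derived from the feature number with 85 features to a row; red points were higher in females and blue points higher in males. The 567 red points thin out towards high feature numbers, and 9 of them lie in the block of highest feature numbers.

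With the 8 samples taken as separate, females varied more among themselves than males did, and the difference did not pass with arrays as the units. The median over features of the SD within a sex was 0.155 on the log2 scale in females and 0.0991 in males, after removal of the mean of each dye, a ratio of 1.56. Per sample, the median absolute deviation from the mean of the sex was 0.0826 to 0.122 in the 4 females and 0.0522 to 0.0812 in the 4 males (two-sided exact permutation test, p = 0.0286, the smallest p that 70 regroupings of 4 against 4 can give). Without any 1 of the 8 samples the difference did not pass, with an exact permutation p of 0.0571 to 0.114. With the local median of the surrounding features subtracted, the ratio was 1.44 and the exact permutation p was 0.0857. Between the array means of a sex the ratio was 2.06, with an exact permutation p of 0.333, the smallest that 2 arrays against 2 can give, and within arrays it was 1.66. With the dye means kept, the ratio was 1.24 and the exact permutation p was 0.143.

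**Figure D4:**
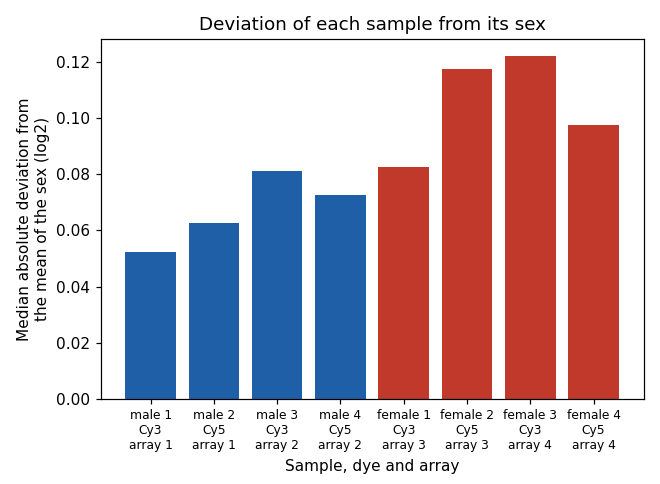
Median absolute deviation of each sample from the mean of its sex (vertical axis, log2), over features with a value in all samples, with the dye and array of each sample below its bar; males are blue and females red. The lowest female bar is at 0.0826 and the highest male bar at 0.0812.

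The first principal component of the values without the dye means held 40.0% of the variance and the second 23.2%. On the first component the female replicates 1 and 2, which shared an array, lay at -38.5 and -45.9, and the other samples between -3.58 and 26.9. On the second the female replicates 3 and 4, which shared the other female array, lay at -35.3 and -32.1, and the other samples between 5.90 and 16.1. The male samples of both arrays lay together on both components.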

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

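The counts of other splits and the tests of the larger spread among females, apart from the local median, were set before their results were seen. The setting without features that differ between the arrays of a sex was itself added after the data were examined. The tests of the counts per block of feature numbers, of neighbouring calls and of features departing on 1 array were chosen only after the results were seen. So was the variability ratio with the local median subtracted.

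Among the 10552 features left out of the tests, 634 had a value in both Cy5 samples of females and in neither Cy5 sample of males, and 145 the reverse. Female Cy5 samples held more values in all, 34560 and 34412 against 33617 and 33739 in males, which alone favours the first kind, and no test was made. Their median male minus female difference in Cy3 was 0.13 and 0.32, while untested features with no Cy5 value in either sex had 0.29. Of 16 sets of 4 values checked within a sex, 1 had a sample far from the other 3, and chance gives about 1 in 20: the densest low level was 1072 steps in female replicate 2, against 233 in the next female, although Cy3 and Cy5 samples are mixed in that set.

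For the 5 features called in the values as deposited, 2 of the 35 splits of the 8 samples into 4 and 4 gave as many calls, the real split included. The other one was the split by dye, a technical split with 16560 calls, which points to the difference between Cy3 and Cy5 as the main structure of the samples; with dye as a term the real split gives its 5, and the highest of the splits not made by dye gave 1. After quantile normalization 1 of the 35 splits, the real one, gave as many. It had 662 calls among features with a value in all samples, against 15 for the highest other, which was the split by dye. At an unadjusted p under 0.05 the split by dye gave more features than the real one, 6758 against 4583. In the values as deposited the real split gave 4127 at that threshold, and mixed-sex splits that divided an array reached 5727 and 5607. The other pairings of whole arrays gave 636 and 886. The samples of an array are not independent, and whole arrays can be paired in only 3 ways, which are too few for a share under 0.05: the real pairing gave 5 calls as deposited and 662 after quantile normalization, and the other pairings 0 each.

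The 567 features higher in females after quantile normalization may come from place on the array surface. The lowest of 4 equal blocks of feature numbers held 237 of them, against at most 180 in 1000 draws of as many features of the same level. A sex difference of the animals as the only source is argued against, since the highest block held 9 where the lowest of 1000 draws had 105. This assumes that probes were placed without regard to what they measure, and levels at adjacent numbers were unrelated (rank correlation 0.00890). The highest block leaned to males as deposited, with 671 male-higher and 268 female-higher features at an unadjusted p under 0.05. An effect of place could thus hide female-higher features there, and the counts cannot exclude a sex difference in the other blocks. At adjacent numbers alone, 32 of the 567 had another of them, within the draws (median 14, highest 39). Subtracting the local median was tried on the values as deposited, not after quantile normalization. The female-higher calls rose there from 4 to 194, 144 of them among the 567, with 75, 56, 52 and 11 in the blocks. The 4 female-higher features called in the values as deposited are among the 567. A sex difference in some of these features stays open, as does whether the effect belongs to the female or the male slide: 0 slides held both sexes, so slide and sex cannot be told apart.

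Both samples of 1 array departed together, by over 1 on the log2 scale from the median of their dye, in 251 features: 140 on the array of female replicates 1 and 2, 59 on that of female replicates 3 and 4, and 27 and 25 on the male arrays. On the array with most of them, 20 had a departing neighbour at the adjacent number, against at most 7 in 1000 random draws, so a local blemish on the array surface is a candidate explanation. Over all 4 arrays 42 had such a neighbour, where the highest draws add up to 15, which argues against a biological difference of the animals for these. That count took adjacent numbers only. With 85 features to a row, some others formed patches across rows, for which no draws were made. On the male arrays, patches lay at rows 65 to 68, columns 50 to 52, and rows 486 to 489, columns 66 to 67. On the female arrays, they lay at rows 118 to 123, columns 70 to 72, and rows 249 to 252, columns 55 to 57. Such patches argue against a biological difference for the features in them. Features lying apart, such as 9181 on the array of male replicates 1 and 2, stay open.

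For the larger spread among females, leaving out features that differed over 2-fold between the arrays of a sex gave a ratio of 1.56, but these were 0.96% of the features and too few to move a median. With the local median subtracted the ratio was 1.44, so local effects on the array surface stay open as part of the source. In the group of brightest features it was 1.55, which argues against the background of dim features. Within arrays it was 1.66, and between arrays 2.06. The contrast within arrays set Cy5 minus Cy3 on 1 array against the same on the other array of the sex. A difference between arrays that both dyes share cancels there, so that alone would not give 1.66. A dye imbalance particular to 1 array does not cancel, so the contrast cannot separate it from a difference between animals. A less even hybridisation of the female slide and a larger difference among female animals were not tested and stay open.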

How the results depend on the processing

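The normexp, array-artefact, simulated-correlation, within-sex dye and local-median settings were chosen only after the data were seen. The count of 5 features was the same with median centring, complete features only and array-artefact features left out. It was 21 (7 higher in males) with no array block, 244 with no dye term, 326 (21 higher in males) with Cy5 samples only, 641 with quantile normalization, 682 with normexp, 235 (41 higher in males) with the local median subtracted, 38 with trend and robust, 11 without the 30% dimmest features and 3 with the simulated array correlation. limma called 0 with array means (3449 at an unadjusted p under 0.05) and 0 with Cy3 samples only (2144). At an adjusted p under 0.01 it called 1, under 0.1 21, and at an unadjusted p under 0.05 with 1.5-fold 765. The quantile and normexp calls held all 5 features, and the local-median calls held 4. A replicate block in place of dye gave 0 calls (4110 at an unadjusted p under 0.05). Removing the dye means makes samples of a dye correlate negatively, with r of -0.352 to -0.09 for the same number and -0.333 to -0.107 for the other; 5 of the 8 samples were closer to their own number, where chance gives 4, so pairing by number was not shown.

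Leaving out 1 sample gave 0 to 146 calls: 146 without female replicate 3, 5 without female replicate 2, and 0 without any of male replicates 1, 2, 3 and 4 or female replicates 1 and 4, where 2493 to 3874 features had an unadjusted p under 0.05. Without an array, calls numbered 9 and 1 (male replicates 1 and 2, male replicates 3 and 4), and 2801 and 6367 (female replicates 1 and 2, female replicates 3 and 4). Of these, 5, 0, 1935 and 2819 were higher in males, and the 9 and 1 held 0 of the 5 features. The last 2 fits had array correlations of -0.398 and -0.353 and held no spread between female arrays. The fit with no dye term had an array correlation of -0.593. The 4 named features kept their direction in all 27 settings; features 7388, 40650, 3851 and 7496 passed in 13, 9, 16 and 16 of them.

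The variability ratio of 1.56 stayed above 1 in every setting run. It was 1.24 (exact permutation p = 0.143) with dye means kept, 2.06 (p = 0.333 by exact permutation, the smallest possible) between array means, 1.44 with the local median subtracted, and 1.40 to 1.68 without 1 sample, where the exact permutation p was 0.0571 to 0.114, with 0.0286 the smallest possible. With dye means removed within each sex it was 1.90 (exact permutation p = 0.0286), and in the other settings 1.503 or higher. Apart from calls lost by a stricter threshold, the cause was not tested. The gene list results, the set tests and the choices among probes of a gene were not run, since features have no gene names here. Whether background limits the dim features in Cy3 is unknown.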

Other observations

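The test of male-limited transcripts was chosen only after the values were seen. A transcript made in males only, as from the Y chromosome, would give a large and steady male excess. Steady features were those whose values on both arrays of a sex lay within 0.5 on the log2 scale in each dye, 25443 in all. A feature with no Cy5 value in the lower sex was kept and set against the 5th percentile there, which took in 87 with no female Cy5 value. Among them 0 had a male excess of 4-fold or more in each dye, and 0 had such a female excess. At 2-fold or more there were 0 higher in males and 9 higher in females, and at 1.41-fold or more 45 and 113. The largest steady difference was 0.96 on the log2 scale on the male side and 1.58 on the female side. After normexp background correction 0 features reached 2-fold on the male side and 48 on the female side. Normexp also moved the median difference of the dimmest 11234 tested features from 0.02 to -0.17, towards females. Features with unsteady values were not covered. The sex of the samples was not checked by gene, since the features carry no gene names here. With 0 of the 25443 steady features at a male excess of 2-fold or more, this search gave no support for the sex labels. The search cannot show the labels wrong, since no feature is known to measure such a transcript.

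In the values as deposited, the dyes differed more than the sexes, and limma called 17487 features between Cy5 and Cy3 at an adjusted p under 0.05. The median Cy5 minus Cy3 difference was -1.29 among the dimmest 11234 features, -0.13 in the middle group and 0.17 among the brightest. After quantile normalization the order of the calls turned: among features with a value in all samples the split by dye gave 15 calls and the split by sex 662. At an unadjusted p under 0.05 the split by dye still gave more features, 6758 against 4583. The fits were not alike: that of the split by sex had a dye term, and that of the split by dye had no sex term.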
